A study of Mus musculus with 2 samples.

How the data were processed

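Single-cell RNA sequencing libraries were compared from the retinas of mice on the C57BL/6 background, 1 labelled wildtype and 1 labelled as a knockout of Igfbpl1, which encodes an insulin-like growth factor binding protein-like protein. Per the labels' protocols, the retinal suspensions of perfused mice were sorted on CD45, a surface protein of leukocytes that microglia also carry, and the design text describes 10 knockout and 10 sex-matched wildtype mice aged 8 to 10 months. The labels do not give the number of mice in each library, the altered allele or its deleted part, and no table used here ties a cell to a mouse. The submitters deposited 1 table of raw counts per library, with genes in rows and cell barcodes in columns. The deposited counts are whole numbers of unique molecular identifiers (UMIs), with no normalization. Per the submitters' processing notes, Cell Ranger 3.1 and the mm10 build were used. Other arms that the design text mentions were not analysed here.

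The table of the library labelled wildtype held 2735 barcodes and 11020717 UMIs (median 3888 per barcode), and that of the library labelled knockout 1785 barcodes and 7945713 UMIs (median 4251). Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 15% mitochondrial counts, which removed 40 and 24. Scrublet, run per library in scanpy 1.11.5, called 8 and 1 doublets, 0.202% of 4456 cells. So low a share means that the caller probably did not work, and doublets must be assumed to remain. The 2687 and 1760 kept cells were scaled to 10000 counts, log-transformed and clustered together (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1), which gave 21 clusters.

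A cluster was named from 24 marker lists fixed before the data were examined. It took the class with at least 3 markers among its 10 leading genes by fold (50 CPM added) or, failing that, the class with the highest relative marker level among those with at least 3 markers detected in 10% of its cells. It stayed unnamed where its leading genes belonged to another class, or where its UMI counts were low (a median below that of the library divided by 3) and no marker led it. This naming rule was settled after clusters had been seen and was the third version tried. The version before it took the highest relative level alone and named several microglial clusters platelet or ganglion cell, from lists with few detected markers; its results are given with the alternatives. A minimum relative marker level of 0.5 was also considered. It was dropped after the leading genes of 1 cluster at a level of 0.312, led by Fabp5, Spp1 and Lgals3, had been seen, so that the inclusion of that cluster among microglia-like cells was a choice made with its genes in view. Of the 21 clusters, 11 were named microglia-like and 1 stayed unnamed.

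Raw counts were summed over the cells of a class in each library and given as CPM, counts per 1000000 of that sum. With 1 library per group there was no replicate, so no test, p-value or standard error is given, and cells were not used as replicates. Intervals are 95% and cover counting error only: exact Poisson for a sum, exact Clopper-Pearson for a share, and for a ratio the exact interval of the split of its counts. Ratios and log2 ratios are those of the library labelled knockout over the library labelled wildtype, with a floor of 3 counts. Genes were counted by size, at a ratio of at least 2 and at least 50 CPM in 1 library. For each of 18 program lists fixed before the data were examined, the median log2 ratio of members with at least 20 CPM in 1 library was set against 10000 random lists of the same size matched on mean expression, as a percentile that describes these libraries, and its counting interval came from 1000 Poisson draws. In 1 list, 1 gene is not analysed here.

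Named genes followed a rule fixed before the data were examined. It took Igfbpl1, the 12 highest and 12 lowest ratios at 50 CPM or more, and from each program list the 2 highest, the 2 lowest and the most abundant member. Genes of ribosomal proteins, mitochondria, predicted genes, sex-linked genes and markers of other classes were left out of the ranking. Classes with at least 50 cells in each library had their 5 highest and 5 lowest genes at 100 CPM or more taken, and each marker list of another class its 2 most abundant members. Ms4a7 was named by that last part. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs, a depth set after the depths but before any thinned result had been seen; 47 and 23 microglia-like cells were shallower and left out. Gene positions came from GENCODE M21 for GRCm38, the assembly also called mm10.

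The comparison step was run on simulated Poisson counts drawn from the microglia-like sums, with 200 genes changed by known folds. Of these, 199 were among the 3137 compared. Its intervals held the true ratio for 94.9% of 2938 unchanged genes, 94% of 50 genes raised 1.5-fold, 100% of 50 raised 2.5-fold and 96% of 50 raised 4-fold. They held it for 93.9% of 49 genes at a ratio of 0.4. As the intervals assume the same Poisson counting, this checks the calculation alone. It does not show that the intervals hold for counts that gather in single cells. Alternatives covered the cell filter, doublets, Leiden resolution, separate clustering, cell-by-cell naming, scaling (TMM from edgeR 4.0.16 in R 4.3.3, median-of-ratios factors, and CPM without ribosomal, mitochondrial and dissociation genes), equal weight per cell, thinning, CPM minimums and an added constant. Another 5, which changed the set of microglia-like cells, were added after the data had been seen. Leaving out a replicate was impossible with 1 library per group.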

Results

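Transcripts were counted in single CD45-sorted cells of the mouse retina, in 1 library labelled wildtype and 1 labelled Igfbpl1 knockout, to compare retinal microglia, the resident macrophages of the tissue, with and without the gene. After filtering, 2687 cells with a median of 3907 UMIs stood in the library labelled wildtype and 1760 cells with a median of 4284.5 UMIs in the library labelled knockout. There was 1 library per group, so every difference below is between 2 libraries, has no replicate check and carries intervals for counting error only.

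Igfbpl1 itself went against the labels. Its gene lies on chromosome 4 of GRCm38, minus strand, from 45809468 to 45826923, with 5 exons, the last and 3′-most from 45809468 to 45811380. The library labelled wildtype held 2 Igfbpl1 counts in 2735 barcodes (0.181 CPM, interval 0.022 to 0.656). The library labelled knockout held 29 counts in 27 of 1785 barcodes (3.65 CPM, interval 2.44 to 5.24). Of those 29 counts, 27 were in 25 of 1471 microglia-like cells (4.14 CPM, interval 2.73 to 6.03) and 2 in the 289 other kept cells. The labels give neither the allele nor its deleted part, and a 3′ tag outside that part would check nothing. Groups are therefore called by their labels throughout, and every direction below is from the library labelled wildtype to the library labelled knockout.

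Microglia-like cells made up most of both sorted libraries. Of their 11 clusters, 1 was named from its leading genes (P2ry12, Gpr34 and Tmem119) and 10 by their relative level of microglia markers; of these 10, 1 had P2ry12 and Cx3cr1 among its leading genes and the others were led by ribosomal, interferon-induced, stress or proliferation genes, among others. Their share was 89.2% of kept cells (interval 88 to 90.4) under the wildtype label and 83.6% (interval 81.8 to 85.3) under the knockout label. The order of these shares was not stable: it turned to 77.4% against 78.8% with a stricter cell filter and to 73.4% against 78% when each library was clustered alone, because clusters led by a few endothelial or bipolar cell genes, and with the stricter filter also 1 led by Spp1, Fabp5, Apoe and Gpnmb (32 and 56 cells), lost their name although 97.4% or more of their cells held at least 3 microglia markers. Monocyte-like cells, led by Plac8 and S100a4, numbered 14 (0.521%, interval 0.285 to 0.873) and 42 (2.39%, interval 1.73 to 3.21). T cell-like cells, led by Ccl5, Nkg7 and Cd3g, numbered 6 (0.223%, interval 0.082 to 0.485) and 20 (1.14%, interval 0.695 to 1.75). Border macrophage-like cells, led by Ms4a7, Apoe and MHC class II genes, were 3.94% (interval 3.24 to 4.75) and 6.19% (interval 5.11 to 7.42). With the stricter cell filter they were 2.45% and 3.44%. The intervals of B cell-like, neutrophil-like, Müller glia or astrocyte-like, rod-like and bipolar cell-like cells overlapped between the libraries. The B cell-like share under the knockout label was 0.511%, but 1.53% when each library was clustered alone. Unnamed cells led by Cldn5, Ly6c1 and Cxcl12 were 1.9% and 1.99%; P2ry12 was counted in 87.2% of them. A sort on CD45 can set all of these shares, and the retinal neurons and glia in them passed it.

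**Figure D1:**
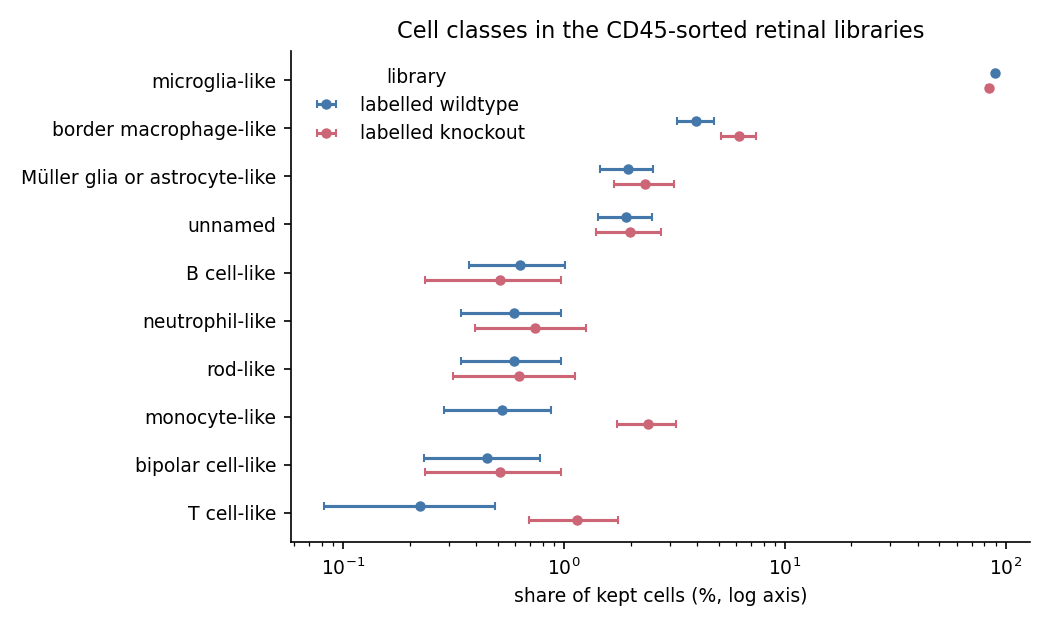
Share of kept cells in each class (x axis, percent, log scale) in the library labelled wildtype (blue) and the library labelled knockout (red), 1 library each; bars are exact 95% binomial intervals for counting error only. Monocyte-like cells lie at 0.521% and 2.39% and T cell-like cells at 0.223% and 1.14%, with intervals that do not overlap.

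Within microglia-like cells (2397 and 1471 cells, 9554131 and 6516310 UMIs), the libraries were close for most genes. Of 3238 genes at 50 CPM or more, 87.1% differed by less than 1.2-fold, 9 were at least 2-fold higher and 4 at least 2-fold lower in the library labelled knockout. Among the highest ratios were 5 members of the disease-associated microglia list (Spp1, Gpnmb, Fabp5, Lgals3 and Apoe). Spp1 (osteopontin, a secreted matrix protein) stood at 9.11 and 146.7 CPM, a ratio of 16.1 (interval 12.9 to 20.3). Gpnmb, a lysosomal glycoprotein gene, had a ratio of 11.7 (interval 8.5 to 16.5), Fabp5, which encodes a fatty acid binding protein, 6.64 (interval 5.82 to 7.6), Vim (vimentin) 2.86 and Lgals3 (galectin 3) 2.78. Apoe, the main apolipoprotein of the nervous system, was by far the most abundant of them, at 1341.9 and 3627.5 CPM, a ratio of 2.7 (interval 2.65 to 2.76). The noncoding RNA AY036118 (2.19), the ribosomal gene Rpl27 (2.16) and the pseudogene Rpl10-ps3 (2.04), which can share reads with near-identical copies, completed the 9. Ccr1, a chemokine receptor gene, followed at 1.95 (interval 1.65 to 2.3), then Crip1 (1.91), Wdr89 (1.75), Ftl1-ps1 (1.73) and Rnaset2a (1.57); the last of these has a near-identical copy too. After thinning, Crip1 was at a log2 ratio of 0.21 and Ftl1-ps1 at 0.33.

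Most of the Spp1, Gpnmb, Fabp5 and Lgals3 counts of both libraries sat in 1 small cluster of microglia-like cells. It held 36 and 37 cells, with median UMI counts of 6869 and 9579 against 3890 and 4251 in the whole class, and its relative level of microglia markers was 0.312. In the library labelled knockout it carried 96.3% of the Spp1 counts, 99.4% of Gpnmb, 96.8% of Fabp5, 97.9% of Lgals3, 88% of Vim and 64.1% of Apoe; in the library labelled wildtype the shares were 75.9%, 90.7%, 88.6%, 91.1%, 47.4% and 36.6%. A single cell of the cluster held 283 of the 956 Spp1 counts under the knockout label. P2ry12 was counted in 56.2% of the cluster's cells, against 90.4% and 88.6% of the whole class. Ms4a7 was counted in 9 of its 36 and 19 of its 37 cells. Whether the cluster's cells are microglia or macrophages derived from monocytes was not tested. Without this cluster 4 genes were at least 2-fold higher and 4 at least 2-fold lower, Gpnmb had too few counts left for a direction, and Vim (-0.56) and Lgals3 (-0.53) turned to the other direction. Spp1 (1.35) and Fabp5 (0.98), both on few remaining counts, and Apoe (0.67) stayed higher without it. Spp1 was at 0.89 with the stricter filter and turned to -1.21 without cells holding 2 or more markers of another class. That last setting kept 1507 of 2397 and 903 of 1471 microglia-like cells. Some of those markers were common in microglia-like cells themselves, with Glul in 75.1% and 74.4% and Ighm in 61.4% and 62.8%. The setting is therefore no measure of RNA from other cells. Under the cluster naming rule tried before the one used, which left this cluster and others out of the class, 2 genes were at least 2-fold higher and 7 at least 2-fold lower. Apoe was also counted in more microglia-like cells, 10.3% (interval 9.1 to 11.6) and 17.8% (interval 15.9 to 19.9) after thinning to 1000 UMIs, and 22.4% and 40.2% unthinned. In rods, bipolar cells and Müller glia, where Müller glia make Apoe, thinned shares were 64.5% and 73.9%, so that Apoe is not a gene whose background these cells can set. The border macrophage marker Ms4a7 was 3.96-fold higher (77 and 208 counts), with 88.5% of its counts under the knockout label in the same cluster.

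Chemokine and interferon-induced genes were among the lowest ratios. Cxcl10, a chemokine gene induced by interferon, stood at 291.1 and 86.7 CPM, a ratio of 0.298 (interval 0.272 to 0.326). Ifit2 and Rsad2, antiviral genes of the same response, had ratios of 0.39 (interval 0.33 to 0.46) and 0.365 (interval 0.281 to 0.47). Ccl5, a chemokine gene, had a ratio of 0.429 (interval 0.386 to 0.476), and Ccl12, a further one, was at 1111 and 619.5 CPM (0.558, interval 0.538 to 0.578). Cxcl10 was counted in 7.79% (interval 6.74 to 8.95) and 2.83% (interval 2.04 to 3.82) of thinned microglia-like cells (13.4% and 6.8% unthinned), against 2.63% and 0% of retinal neurons and glia. The corresponding shares for Ccl5 were 5.7% and 2.56% (9.18% and 5.1% unthinned), against 0% and 0%. Ifit3, at a ratio of 0.607, was counted in 5.57% and 5.59% of thinned microglia-like cells, Ifit2 in 3.79% and 2.49% and Rsad2 in 1.91% and 1.04%. Under the knockout label these shares lay below those in 46 retinal neurons and glia (15.2%, 8.7% and 4.35%), so no difference is read from them; in 76 such cells under the wildtype label the shares were 5.26%, 1.32% and 0%. Gdf15, a stress-induced cytokine gene, had a ratio of 0.304, but 544 of its 718 counts under the wildtype label came from 1 cell. Hist1h1e (0.544), March1 (0.615), Nsun6 (0.623), Pfkfb3 (0.63), H2-Q6 (0.643, from a multigene family) and Ppp1r10 (0.649) completed the 12 lowest. When cells were named one by one, Ccl5 lost its direction (log2 ratio 0.13).

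**Figure D2:**
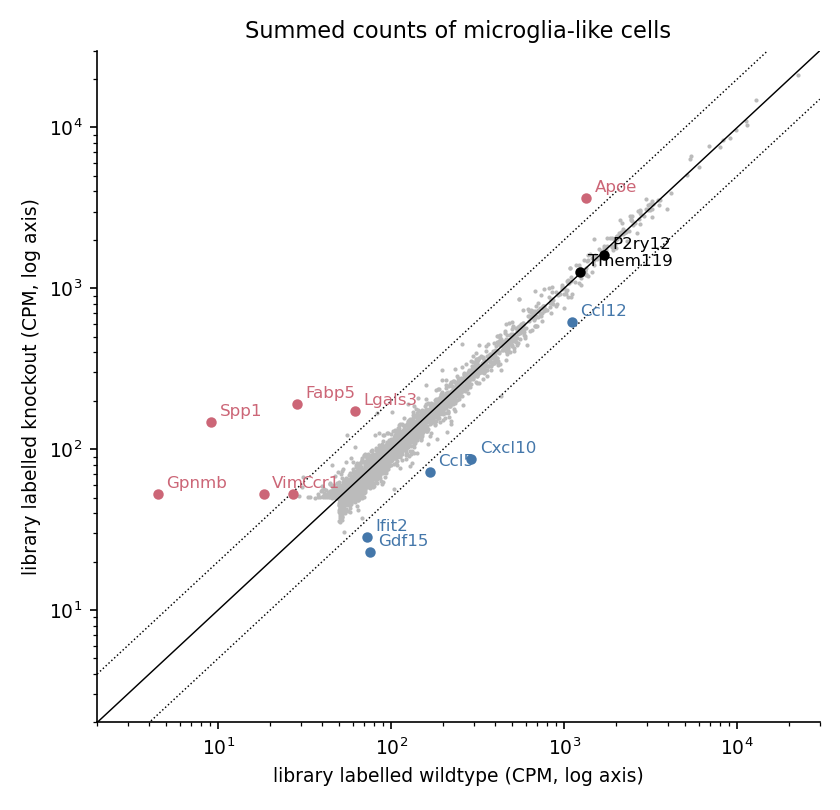
CPM of summed counts of microglia-like cells in the library labelled wildtype (x axis) and the library labelled knockout (y axis), both log scale, for genes at 50 CPM or more in 1 library. Each point is a gene, the solid line marks equal levels and the dotted lines 2-fold; named genes at least 1.5-fold higher are red, lower blue, others black. Apoe lies at 1341.9 and 3627.5 CPM and Cxcl10 at 291.1 and 86.7 CPM, while P2ry12 and Tmem119 lie near the line of equal levels.

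The homeostatic microglia list, which holds genes of resting microglia, did not part the libraries. All 28 members were measured and lay between 1.5-fold lower and 1.5-fold higher, with a median log2 ratio of -0.01 (interval -0.04 to 0.01) at percentile 21.8 of matched random lists. The extremes were Fcrls, at a ratio of 0.672, and Slc2a5, a sugar transporter gene, at 1.28; Cst3, the most abundant, was at 1.02. Of 25 measured disease-associated microglia genes, 5 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.10 (interval 0.07 to 0.16) at percentile 99.9. Ctsd, the cathepsin D gene, was its most abundant member at 1.22, and Csf1, at 0.88, was the lowest. That median was 0.02 without the Spp1-led cluster and -0.02 under the earlier naming rule. Lipid and cholesterol handling genes, with 2 of 15 at least 1.5-fold higher (Apoe and Fabp5) and 0 lower, had a median of 0.14 at percentile 99.9, which was 0.03 after thinning and 0.37 at a minimum of 100 CPM; Hmgcs1 (0.807) and Insig1 (0.815), of cholesterol synthesis and its control, lay lowest.

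Of 27 interferon response genes, 7 were at least 1.5-fold lower and 1, Ifi27l2a (1.55), was higher. Their median log2 ratio of -0.11 had an interval that spanned 0 (-0.21 to 0.03), at percentile 2.67, and turned to 0.14 among members at 100 CPM or more, where 5 of the 7 lower members did not reach; it was 0.10 with equal weight per cell and -0.34 with called doublets kept. Inflammatory cytokines and NF-kB targets were below a ratio of 1 for 20 of 25 members, with a median of -0.14 (interval -0.21 to -0.08) at percentile 0.1. A cluster led by Ccl2, Hspa1b, Ccl3 and Socs3, which held 350 and 121 of the 2397 and 1471 microglia-like cells, is part of this value; without it the median was -0.11. Of the members, 2 were at least 1.5-fold lower: Ccl12 and Cxcl2 (0.508), the second of which had 70.8% of its wildtype-labelled counts in the Spp1-led cluster and turned to a log2 ratio of 0.84 without it. Ccl4 was the most abundant (0.841), and Cd83 was at 1.27. The dissociation and immediate early list, which responds to warm enzymatic digestion, had a median of -0.06 at percentile 5.23, with Jun at 0.789 and Atf3 at 1.37; the median was -0.20 after thinning, -0.14 with equal weight per cell and 0.008 with the stricter filter.

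Energy metabolism differed by little. Oxidative phosphorylation genes were above a ratio of 1 for 29 of 34 members, with a median log2 ratio of 0.05 at percentile 99.6 and none past 1.5-fold. Glycolysis and hypoxia genes had a median of 0.08 at percentile 99.2, with Gapdh at 1.2, Slc2a1 (a glucose transporter gene) at 1.46 and Bnip3 at 0.664, the 1 of 16 beyond 1.5-fold. Under the earlier naming rule these 2 medians were -0.003 and -0.02, and without the Spp1-led cluster they were 0.016 and 0.036. With the stricter filter the oxidative phosphorylation median was 0.003. Iron and oxidative stress genes had a median of 0.10 at percentile 99.5, with Fth1 (ferritin heavy chain) at 1.11, but this median was -0.04 after thinning, 0.004 without the Spp1-led cluster and 0.03 with the stricter filter. Cell cycle genes had a median of -0.18 at percentile 3.75 from 6 measured members, among them Stmn1 at 0.727; it ran from -0.47 without the Ccl2-led cluster to 0.04 without cells holding markers of another class. The medians of the remaining lists, on antigen presentation by MHC class I (-0.06, percentile 18.4) and class II (0.01, percentile 62.5), complement (-0.01, percentile 37.6), lysosome and phagocytosis (0.02, percentile 67.8), resolution of inflammation (-0.02, percentile 54.2), unfolded protein (0.02, percentile 76.8) and the insulin-like growth factor system (0.03, percentile 74.7, 4 members), lay nearer the middle of random lists. Sex-linked genes had a median of -0.17 at percentile 14.7 from 3 measured members. The median of the insulin-like growth factor list was not stable, at 0.28 after thinning, 0.36 under the earlier naming rule and -0.06 without the Spp1-led cluster.

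**Figure D3:**
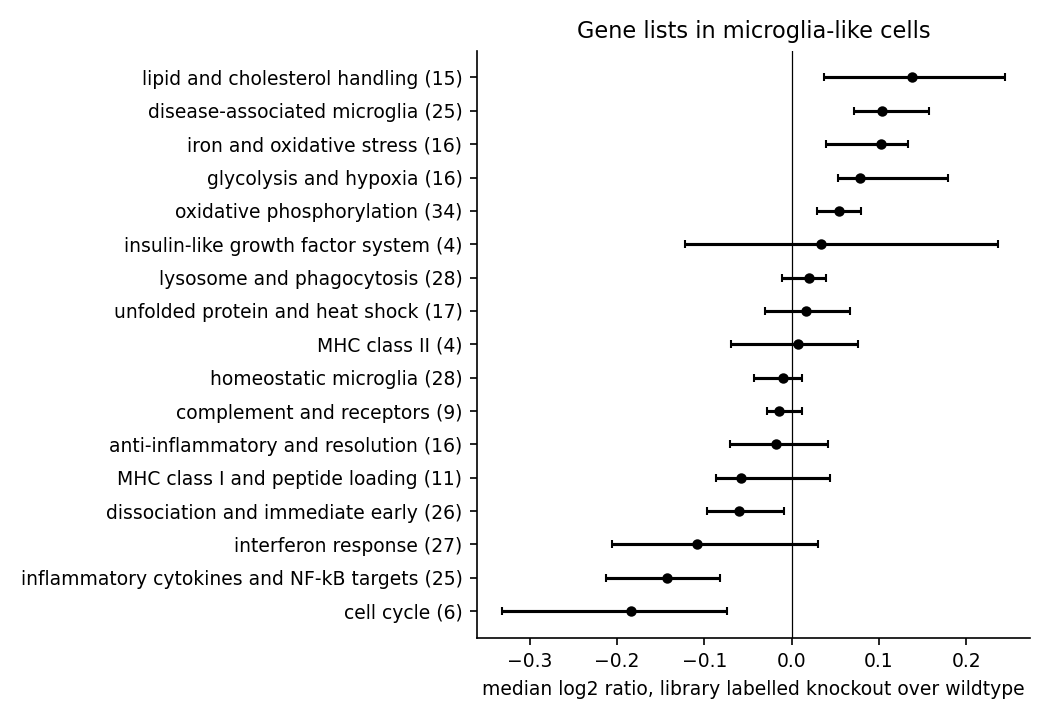
Median log2 ratio of each program list except the sex-linked one in microglia-like cells (x axis, library labelled knockout over wildtype). The number of measured genes is in brackets, and bars are intervals from Poisson draws, for counting error only. Medians run from -0.18 for cell cycle to 0.14 for lipid and cholesterol handling, and the homeostatic list lies at -0.01.

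Border macrophage-like cells (106 and 109 cells, 431988 and 431343 UMIs) were the other class with at least 50 cells in each library. Of 1379 genes at 100 CPM or more, 14 were at least 2-fold higher and 14 at least 2-fold lower, on counts that were often small. Cd5l, a scavenger protein gene of macrophages, was highest (6 and 50 counts, ratio 8.35, interval 3.58 to 23.8), followed by Cxcr4 (3.25), Chordc1 (3), Sox4 (2.94) and Adamts1 (2.73). The 5 lowest were Cxcl2 (233 and 55 counts, 0.236, interval 0.173 to 0.318), Cxcl10 (114 and 31 counts, 0.272, interval 0.177 to 0.408), Ccl5 (49 and 15 counts, 0.307, interval 0.16 to 0.556), Tox4 (0.353) and Ccrl2 (0.36). Giving each cell equal weight brought Ccl5 there to a log2 ratio of -0.24 and Adamts1 to 0.44. P2ry12, a microglia marker, was counted in 55.7% of the cells of 1 of the 2 clusters of this class and in 14% of the other. How far RNA of microglia enters these values was not tested. Apoe, at 1.21, differed far less than in microglia-like cells.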

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

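The alternatives that removed cells or renamed clusters after the data had been seen are those without the Spp1-led cluster, without the Ccl2-led cluster, without low-count clusters, without cells holding 2 or more markers of another class, and with clusters named by the highest relative marker level alone, the rule tried before the one used. Leaving out cells with such markers kept 1507 and 903 cells. Microglia-like cells themselves held some of these genes, so this alternative is no measure of RNA from other cells. Of the values recomputed under all alternatives, 820 stayed within their counting interval or count range, 161 moved beyond it and 10 reversed. Only genes at least 1.5-fold apart in the main analysis could be called reversed. List medians that changed sign and shares that changed order are therefore counted among the 820 or the 161. Scaling shifted all log2 ratios by 0.014 to 0.023. Cxcl10 kept at least a 1.5-fold lower level in all 16 alternatives (log2 -2.03 to -1.27), as did Ifit2, Rsad2 and Ccl12, and Apoe stayed higher in all 16 (0.58 to 1.56). The inflammatory list stayed below 0 in all 19 of its alternatives and the homeostatic list fell on both sides of 0. The share of microglia-like cells under the wildtype and knockout labels was 77.39% and 78.77% with the stricter filter, 73.43% and 78.01% with libraries clustered alone, 83.71% and 74.9% with called doublets kept, 95.12% and 92.5% with cells named one by one, 90.92% and 85.4% at resolution 0.5, 90.84% and 85.34% at resolution 2, and 48.23% and 47.9% under the earlier naming rule. In the first 3 of these the clusters that lost their name (with the stricter filter 365 and 121 cells led by Gng13 and Pcp2, and 32 and 56 led by Spp1, so that this filter overlaps with leaving out the Spp1-led cluster) account for the fall, as 97.4% or more of their cells held microglia markers. The stricter filter also gave border macrophage-like shares of 2.447% and 3.438%, bipolar cell-like shares of 0% in both and a rod-like share of 0.3016% under the knockout label. Every deposited cell kept gave 1.625% Müller glia or astrocyte-like and 1.064% bipolar cell-like, and separate clustering 1.534% B cell-like, all under the knockout label; the cause was not tested. Genes at least 2-fold higher numbered 4 with the stricter filter, 4 without the Spp1-led cluster, 4 without cells holding other markers, 1 at a minimum of 200 CPM and 2 under the earlier naming rule, against 9. Genes at least 2-fold lower numbered 9 at a minimum of 20 CPM, 1 at 200 CPM and 7 under the earlier rule, against 4. The homeostatic median was 0.013 with median-of-ratios factors, 0.042 with the stricter filter, 0.038 without the Spp1-led cluster and 0.041 under the earlier rule. Log2 ratios reversed without the Spp1-led cluster for Vim (-0.5554), Lgals3 (-0.5324), Gdf15 (0.2804) and Cxcl2 (0.8442), since that cluster held most of their counts in at least 1 library. They reversed under the earlier rule for Vim (-0.7258), Lgals3 (-1.489) and Gdf15 (0.4256), without cells holding other markers for Spp1 (-1.208) and Gdf15 (0.4535), and with cells named one by one for Ccl5 (0.1263); the cause was not tested for these. Leaving out each library in turn was not run, as 1 library per group leaves no comparison. Igfbpl1 rests on 2 counts against 29. No paired analysis was possible because each group held 1 library.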

Other observations

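Sex-linked transcripts showed cells of both sexes in each library. Under the wildtype label, 692 microglia-like cells held Xist and no Y-linked count and 665 held Y-linked counts alone; under the knockout label the numbers were 382 and 412. Both kinds were counted together in 21 and 2 cells, 0.876% and 0.136%. In border macrophage-like cells, MHC class II genes lay lower under the knockout label, with Cd74 at a ratio of 0.622 (interval 0.596 to 0.65), H2-Eb1 at 0.744, H2-Aa at 0.759 and H2-Ab1 at 0.81; these genes were chosen after their values had been seen.

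Of the tests below, those on the neighbours of Igfbpl1 and on the dissociation response were set before their result was seen; the others were chosen after it. A first version of the tests on RNA from other cell types summed all their markers and was replaced once seen, because microglia themselves hold much Glul, Slc1a3, Stab1 and Cd74. A first version of the test on a few cells for Spp1, Gpnmb, Fabp5, Lgals3 and Apoe left out the Spp1-led cluster, which gave a median log2 ratio of 0.67 over genes that went both ways, and was replaced too. For the interferon and chemokine genes the first version left out the 10 cells with most counts. These are a larger part of the smaller library, which lowers its level, so that version was replaced by shares of cells after thinning. For genes higher under the knockout label the step was kept. Microglia-like cells with a count numbered 537 and 592 for Apoe, 46 and 53 for Fabp5 and 42 and 42 for Lgals3. For Apoe and Fabp5, 10 cells are thus a somewhat larger part of such cells under the wildtype label. Leaving them out can raise the ratio, so the step can favour the pattern for these genes. H2-Aa, H2-Eb1, Pf4 and Mrc1 were each added to the border macrophage test after its first value and that of Ms4a7 had been seen.

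The Igfbpl1 counts under the knockout label were not part of a change across the locus, since 22 genes within 1000000 bases had a median log2 ratio of -0.0874 and none lay above 0.413. An exchange of the 2 library labels may account for them, as may an allele that keeps the 3′ end of the transcript: the ratio over all kept cells, from 1 count under the wildtype label and so with the floor of 3 counts, was 13.4 (lower limit without the floor 6.65), and no other measured value marks the genotype, so these cannot be told apart. Free RNA stays open too, because the other kept cells, at 1.44 CPM (interval 0.174 to 5.18), were too few to set against the 4.14 CPM of microglia-like cells.

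The lower chemokine and interferon genes under the knockout label (9 genes, median log2 ratio -0.889) were picked from these same data. They are the 7 interferon response members at least 1.5-fold lower, with Ccl5 and Ccl12 added. Matching the cells of both libraries on the share of their counts in dissociation genes moved that share from 2.04% to 2.27%, against 2.22% under the wildtype label, and left the median at -1.01. Matching on this share thus did not remove the difference. As the share differed little before matching, the test could hardly move the median, and a weaker response to dissociation is not excluded. Whether a few cells with very large counts are the cause stays open. The shares of cells with a UMI, after thinning, had a median log2 ratio of -0.296, with genes from -1.46 (Cxcl10) to 0.469 (Ifit3b). This median includes Ifit2, Ifit3 and Rsad2, from whose shares no difference is read above. Genotype, differences between the mice pooled and between sorts or library preparations stay open, untested, as each group was 1 library.

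Higher Apoe, Spp1, Gpnmb, Fabp5 and Lgals3 under the knockout label were not brought by RNA of Müller glia, whose markers that microglia lack (14 and 22 counts) could carry at most 0.273% of the difference of any of the 5 genes. Border macrophages could carry at most 8.25% by the sum of such markers (51 and 26 counts). Of single genes, H2-Aa would allow 13.6% and Mrc1 (5 and 6 counts) 34.2%. Ms4a7 alone (77 and 208 counts, 88.5% of the latter in the Spp1-led cluster) would allow 74.1% for Apoe and at most 1.01% for the other 4 genes. Cells with the make-up of the border macrophage-like class would bring H2-Aa too, but cells with Ms4a7 and little H2-Aa were not tested. This source is therefore not excluded for Apoe. All these percentages refer to the difference over the whole class, with the Spp1-led cluster. Shares of the smaller Apoe difference outside that cluster were not computed. Macrophages derived from monocytes were not tested for any of the 5 genes. Without the 10 cells of each library with most counts the log2 ratio was 1.51 for Apoe. The median of Fabp5 (54 and 210 counts left) and Lgals3 (87 and 145) was 1.92. The difference in these 3 genes thus did not rest on 10 cells alone. A small group of cells is not excluded, as the Spp1-led cluster (36 and 37 cells) is larger than the number left out. Without that cluster the log2 ratio was 0.67 for Apoe, 0.98 for Fabp5 and -0.53 for Lgals3. For Spp1 (14 and 18 counts left) and Gpnmb (1 and 33) the median of 2.48 rests on too few counts to decide. A hypothesis that these data leave untested is that microglia-like cells with lipid-handling genes differ between the genotypes; it would need replicate libraries whose genotype is checked.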
